A study of Mus musculus with 6 samples.

How the data were processed

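Hepatocytes were collected from livers of C57BL/6J mice that carried floxed Ncaph2 alleles and a Cre under the transthyretin (Ttr) name in the genotype label, after tamoxifen. Per the labels' protocols, mice of 12 weeks received 1 mg tamoxifen on each of 5 days and were kept for 5 further days before perfusion of the liver with collagenase and low-speed spins that enrich hepatocytes. The labels hold 6 samples, 4 of RNA-seq and 2 of Hi-C by tethered chromosome capture, a form of Hi-C in which ligation takes place on a solid support. Per the labels' protocols, RNA libraries were depleted of ribosomal RNA, made strand-specific and sequenced as single reads of 50 bp. Hi-C contact data were not analysed here, so no statement on chromatin folding is made.

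The values come from 1 table of gene-level comparisons. The submitters' processing notes name STAR 2.5.0a, HTSeq, DESeq2 and BWA and the mouse build mm9, without saying which step used which. The authors' mean normalised count of each side is a signal value. It was read as a read count divided by a library size factor and averaged over libraries. That reading rests on the column names and on the steps of the low means described below. The fold change is the ratio that the authors deposited, the Ncaph2-deleted mean divided by the control mean, and the log2 fold change that the authors deposited is its logarithm with no pseudocount and no shrinkage. The p-value and adjusted p-value are also those the authors deposited. Column names in the file are those of the older DESeq package, per the file headers, so which version of the authors' tool made them is not given in the sources used here. The adjusted p fits a Benjamini-Hochberg adjustment over 22224 tests, since 44 of the 58 genes called have a whole-number rank at that total (tolerance 0.001), and 14927 genes were analysed here. Side A was read as the tamoxifen control and side B as Ncaph2-deleted from the order of names in the table's title, and the lower Ncaph2 mean on side B goes with that order. The mean over both sides equalled the average of the side means in all 14927 genes (relative tolerance 1e-05).

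The table has no column per library and the labels hold no control RNA sample, so no count test could be run, and the authors' own test was taken as it stands, with a threshold of 0.05 on the adjusted p. This is the fallback that the fixed design named for a table without library counts. Low means on each side were sums of whole multiples of 4 steps, which gives 4 libraries a side and their relative depth, but not the reads of a gene in a library. This step search recovered 4 simulated size factors with an error of at most 1.44e-05%. From these factors, depth in the listed genes was about 4059636 to 13655232 reads per control library and 12471015 to 18053472 reads per Ncaph2-deleted library.

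A signed z was made from each p and the sign of the log2 fold change. A standard error was implied by dividing the log2 fold change by that z, and 95% intervals rest on it. It is unreliable where the log2 fold change lies near 0. Gene lists fixed before the data were examined (31 lists, 424 members, of which 368 were measured in 30 lists) were tested on z with cameraPR of limma 3.58.1 in R 4.3.3, 2-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 30 lists. Because no library columns exist, the correlation could not be estimated from the data, so a correlation of 0.05 was run beside it. On shuffled statistics, 93% of simulated lists of 15 genes shifted by 1 in z passed and 3% of unshifted lists passed, with 100 lists of each kind over 14927 genes. Median log2 fold changes were also set against 100000 lists drawn from the same expression deciles. In its simulated test, 100% of 20 lists shifted by 0.5 and 0% of 20 unshifted lists had a p below 0.05. The simulations of the list test and of the matched draws shuffled values over genes, which removes correlation between genes. Their rates therefore do not give the share of false calls for lists of correlated genes. Terms of the gene ontology in the table were tested by Fisher's exact test over 10091 annotated genes with a mean of at least 10, for terms of 10 to 500 genes, leaving out 837 genes without a usable annotation. Planted terms were found in 100% of 10 simulated draws, and 0 of 10 random draws gave a term. Other analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

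Named genes followed a rule fixed in advance. It takes all members of both condensin complexes, the 10 highest and 10 lowest log2 fold changes among genes with an adjusted p below 0.05 and a mean normalised count of at least 50 (all of them where fewer pass), and from each list up to 4 members with the smallest p where the list or a member passed, otherwise up to 2. Some genes that the rule takes are not reported here. Outside the rule, Alb was named for its share of the sums. Genes under Other observations that the rule does not take, among them Nop58, Herpud1, Klf9 and Sgk1, were named after the results were seen. Alternatives were other thresholds, Benjamini-Hochberg over other gene sets, an empirical null, centring, other list tests and other expression limits. Symbols are those of the table, and 14730 gene IDs were found in the reference name table. Overlapping genes and near-identical family members can share reads, and how the authors counted these is not given in the sources used here.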

Results

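The study asked, per its title, whether loss of condensin II in non-dividing cells alters chromatin folding or gene expression. Condensin II is a ring-shaped protein complex that compacts chromosomes for mitosis and stays in the nucleus during interphase, and Ncaph2 encodes its kleisin subunit, which closes the ring. RNA was measured in hepatocytes of tamoxifen-treated mice with deletable Ncaph2, in 4 RNA-seq samples. The authors compared these with hepatocytes of tamoxifen-treated controls, which are not among the labelled samples and enter only as a mean. The means summed to 10941337 normalised reads for control and 10902181 for Ncaph2-deleted hepatocytes in the authors' deposited table, and albumin (Alb) took 13% of the control sum and 14.4% of the Ncaph2-deleted sum. Library size factors recovered from the low values were 0.371, 0.819, 0.839 and 1.25 for the control libraries and 1.14, 1.31, 1.33 and 1.66 for the Ncaph2-deleted libraries, so controls were the shallower side. Spread between libraries enters only through the authors' p, and nothing per library can be given. The design text calls the RNA samples replicates without naming separate animals. The authors' p per gene therefore measures the spread between libraries, which need not be separate animals. P-values of the list, matched-draw and gene ontology tests measure the spread between genes, not between libraries.

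The targeted gene was lower but did not pass the authors' test. Ncaph2 (ENSMUSG00000008690, chromosome 15, 89186150 to 89203257, mm9) averaged 418 normalised reads in control and 239 in Ncaph2-deleted hepatocytes in the authors' deposited table, a log2 fold change of -0.81 with p = 0.00549 and an adjusted p of 0.457. The 95% interval implied by that p ran from -1.37 to -0.24. Exons outside the deleted part can still be counted, and gene-level values cannot separate such reads from intact transcript. All other condensin II members had higher means in Ncaph2-deleted cells, none past the adjusted threshold. In the authors' deposited table the log2 fold change was 1.34 for Smc2 and 0.89 for Smc4, the ATPase subunits shared by both condensins, 1.33 for Ncapg2 and 0.28 for Ncapd3. Condensin I, which acts after nuclear envelope breakdown, had log2 fold changes of 1.34 for Ncaph, 1.11 for Ncapd2 and 2.15 for Ncapg in the authors' deposited table, with adjusted p of 0.292, 0.351 and 0.0814. Adjusted over the list alone, 3 of 5 condensin II genes rose and 1, Ncaph2, fell, and 3 of 3 condensin I genes rose, against 0 in either list over all genes. As lists, condensin II (median log2 0.89, cameraPR adjusted p = 0.00187) and condensin I (median 1.34, adjusted p = 2.88e-09) rose, the first of them losing its call in a test on ranks (adjusted p = 0.0786). Of the 3 condensin I genes, Ncaph and Ncapg had means over both sides of 36.1 and 47.0. Condensin I could therefore not be tested as a list with a mean of at least 50 required. The condensin II list holds the shared Smc2 and Smc4, and its median is the value of Smc4. Of the subunits not shared, Ncaph2 fell, and in the authors' test Ncapd3 had p = 0.347 and Ncapg2 an adjusted p of 0.593. The list thus does not single out condensin II. Genes next to Ncaph2 on chromosome 15 fell as a list, with 14 of 15 lower, a median of -0.27 and an adjusted p of 0.00866, although 0 of them had an unadjusted p below 0.05 in the authors' test, and the list missed the threshold against expression-matched draws (adjusted p = 0.0584) and regardless of sign (adjusted p = 0.589). Their leading members were Arsa at -0.50, Plxnb2 at -0.52, Tymp at -0.29 and Mapk11 at -0.91 in the authors' deposited table.

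**Figure D1:**
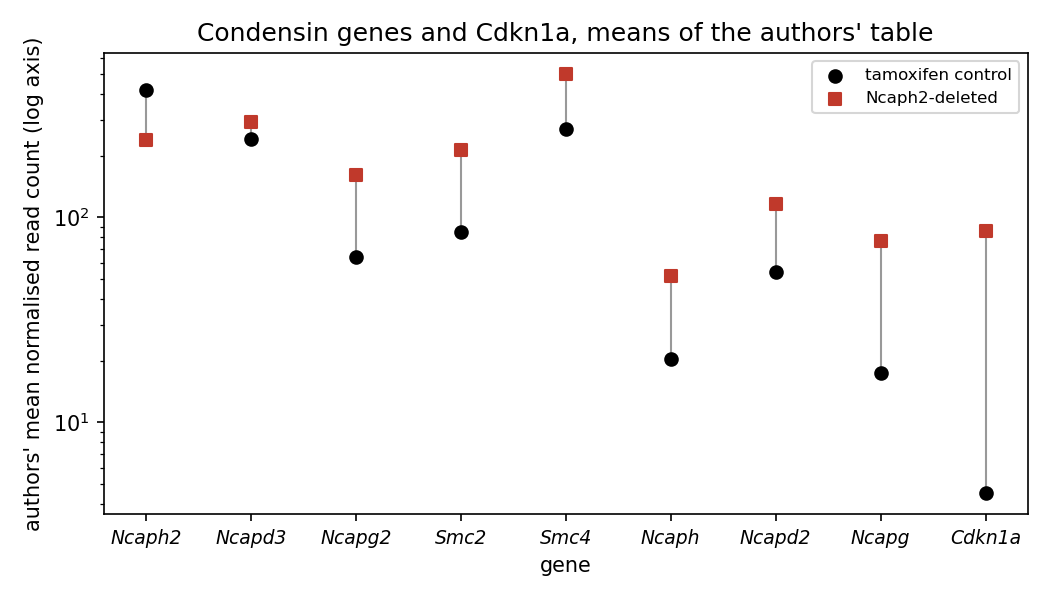
Authors' mean normalised read counts (log axis) of the condensin II genes Ncaph2, Ncapd3, Ncapg2, Smc2 and Smc4, the condensin I genes Ncaph, Ncapd2 and Ncapg, and Cdkn1a, with circles for the tamoxifen control mean and squares for the Ncaph2-deleted mean; no error can be drawn because the table gives means only. Ncaph2 went from 418 to 239 while Cdkn1a went from 4.51 to 86.2.

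Few genes passed, and most of those were higher after deletion of Ncaph2. An adjusted p below 0.05 was given for 58 of 14927 genes in the authors' deposited table, 50 of them higher and 8 lower in Ncaph2-deleted hepatocytes. All 58 had an absolute log2 fold change of at least 1. Mean normalised counts were below 50 in 16 of them. Unadjusted p was below 0.05 for 635 genes (4.25%). The 5% expected by chance holds only for calibrated p-values. The robust spread of z was 0.771 over genes with a mean of at least 50, narrower than a standard normal. The share thus does not show whether small p-values were in excess. The smallest p belonged to Cdkn1a (p21, an inhibitor of cyclin-dependent kinases), which rose from 4.51 to 86.2 normalised reads in the authors' deposited table, 19.1-fold, with an adjusted p of 1.5e-11.

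Among called genes with a mean of at least 50, the highest log2 fold changes in the authors' deposited table included several genes of chromosome segregation. They were 2.86 for Kntc1 and 2.48 for Cenpe, both kinetochore genes, 2.47 for D2Ertd750e, 2.45 for Gstm3, a glutathione transferase, 2.36 for Tpx2, a spindle assembly factor, 2.33 for Ckap2 and 2.20 for Kif20b, a mitotic kinesin. The remaining members of that top 10 in the authors' deposited table were Plin4, a lipid droplet coat protein, at 2.27 (adjusted p = 3.16e-07), Ddit4, an inhibitor of mTORC1, at 2.24 and Mfsd2a, a lysophospholipid transporter, at 2.21. The 8 genes that fell were Nr1d1 (REV-ERB alpha, a repressor of the circadian clock) at -1.82 with adjusted p = 0.000113, Bhlhe41 at -1.61, Rnf152 at -1.54, Fgfr2 at -1.46, Rgs3 at -1.25, Tbc1d30 at -1.14, Flcn at -1.04 and Slc23a2 at -1.02 in the authors' deposited table. Rnf152 and Tbc1d30 passed narrowly there, with adjusted p of 0.04998 and 0.0491.

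**Figure D2:**
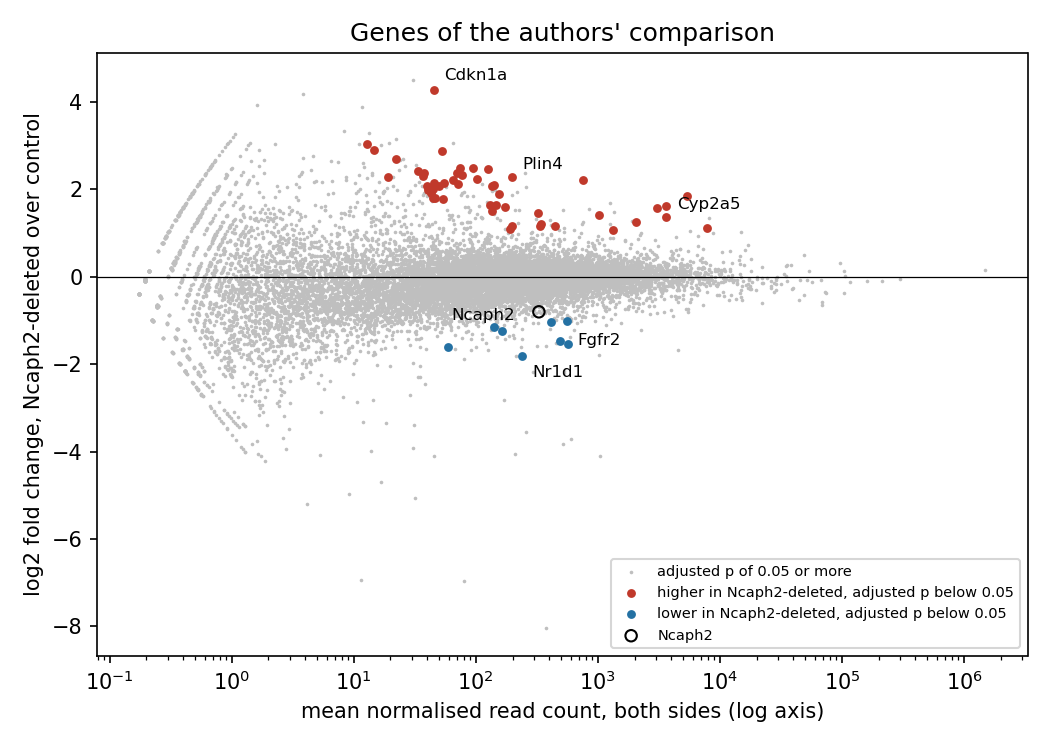
Log2 fold change of Ncaph2-deleted over control against the mean normalised read count of both sides (log axis), 1 point per gene with a finite log2 fold change in the authors' table. The 50 genes called higher (red) and 8 called lower (blue) all lie at an absolute log2 fold change of at least 1, and Ncaph2 (ring, -0.81) was not called.

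Cell division genes rose together. All 18 mitotic genes of the fixed list had higher means, with a median log2 fold change of 1.94 (cameraPR adjusted p = 3.38e-40). The authors' test called 2 of them and left 16 not passing, and adjusted over the list alone 16 rose. Cenpe and Tpx2 were the called members, while Cdk1 at 1.86 and Ccna2 at 1.94 had adjusted p of 0.055 and 0.0601 in the authors' deposited table. All 17 DNA replication genes were higher too, with a median of 1.23 (adjusted p = 6.03e-29), 1 called and 13 called when adjusted over the list alone. Mcm4, a subunit of the replicative helicase, rose 2.84-fold in the authors' deposited table, and Rrm2 at 1.97, Gins2 at 2.37 and Mcm6 at 1.94 did not pass there. Of the p53 targets, 13 of 17 were higher, with a median of 0.31 (adjusted p = 1.09e-09), 1 called and 3 called when adjusted over the list alone. Besides Cdkn1a, Eda2r at 2.11, Phlda3 at 1.53 and Ccng1 at 0.66 led that list in the authors' deposited table without passing. Cohesin and its regulators did not pass as a list (9 of 14 higher, adjusted p = 0.168, 0 called, 1 adjusted over the list alone). Esco2 at 2.04 and Cdca5 (sororin) at 1.88, which set up and protect cohesion between sister chromatids, led it in the authors' deposited table.

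Detoxification genes rose. Among 12 measured members of the xenobiotic response list 11 were higher, with a median of 1.01 (adjusted p = 2.49e-16). The authors' test called 3 of them, 9 did not pass, and adjusted over the list alone 6 rose. The called genes in the authors' deposited table were Gstm3, Cyp2a5 at 1.36 (2044 to 5238 normalised reads) and Nqo1 at 1.58, with Gstm1 at 1.00 not passing (adjusted p = 0.0814). Cholesterol synthesis genes fell as a list, with 17 of 17 lower and a median of -0.52 (adjusted p = 1.96e-09), though 0 were called over all genes or adjusted over the list alone. In the authors' deposited table the members with the smallest p were Fdft1 at -0.85, Dhcr7 at -0.62, Mvk at -0.83 and Sc4mol (Msmo1) at -0.81.

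Clock genes went both ways. Nr1d1 and Bhlhe41 fell, 15 of the 17 members measured did not pass, and adjusted over the list alone 1 rose and 3 fell. Dbp at -1.01 and Gm129 (Ciart) at 0.95 had adjusted p of 0.246 and 0.271 in the authors' deposited table. As a list the clock genes did not move to 1 side in the main test (adjusted p = 0.392, test direction lower, median 0.19). Against expression-matched draws the median was higher (adjusted p = 0.0236). In the test regardless of sign, chosen after the data were seen, the list passed (cameraPR adjusted p = 9.91e-13).

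Other metabolic lists did not pass in either single direction in the main test, though the median of PPARalpha targets was higher against expression-matched draws (adjusted p = 0.0476). Lipogenesis and glycolysis had 6 of 13 members higher (median -0.08, test direction higher, adjusted p = 0.601), with Thrsp at 1.03 in the authors' deposited table. PPARalpha targets had 9 of 15 higher (adjusted p = 0.195), led by Acot2 at 0.87 and Cyp4a14 at 0.92 in the authors' deposited table. For gluconeogenesis and amino acid catabolism, 7 of 11 were higher (adjusted p = 0.0841), with Tat at 1.01 and Sds at 0.85 in the authors' deposited table. Bile acid genes had 5 of 13 higher (adjusted p = 0.68), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 0.90 and Abcb11 at -0.50 in the authors' deposited table. In a test regardless of sign, chosen after the data were seen, lipogenesis and glycolysis (adjusted p = 0.00614) and gluconeogenesis and amino acid catabolism (adjusted p = 0.00515) passed, and the other lists of this group did not (0.478 for PPARalpha targets and 0.589 for bile acid genes). None of these 4 lists had a member called over all genes, and adjusted over the list alone they had 1, 0, 2 and 1.

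Of the lists for liver zones and sex-biased genes, pericentral and male-biased genes passed. Pericentral hepatocyte genes passed in the direction of higher expression (8 of 12 higher, median 0.17, adjusted p = 0.0358) through Cyp2a5, which the xenobiotic list also holds. The list lost its call without the called gene (adjusted p = 0.378), at an inter-gene correlation of 0.05 (adjusted p = 0.0954), by ranks (adjusted p = 0.107), with a mean of at least 50 (adjusted p = 0.0858) and against expression-matched draws (adjusted p = 0.06), and passed regardless of sign (adjusted p = 9.7e-05). Besides Cyp2a5, Lgr5 at -1.10, Slc1a2 at 0.55 and Tbx3 at -0.43 in the authors' deposited table went both ways. Adjusted over the list alone, 1 pericentral gene rose and 1 fell. Periportal genes did not pass as higher or lower (6 of 11 higher, adjusted p = 0.392, 0 called, 2 adjusted over the list alone) but passed regardless of sign (adjusted p = 0.000889), with Agxt2l1 at 1.27 and Sds in the lead in the authors' deposited table. Male-biased genes fell as a list, with 6 of 7 measured lower (median -0.75, adjusted p = 0.0024) and 0 called over all genes or adjusted over the list alone. Hsd3b5 at -3.40, Elovl3 at -1.41, Slco1a1 at -0.75 and Ugt2b38 at -1.02 had the smallest p there in the authors' deposited table. With a mean of at least 50 required, that list no longer passed (adjusted p = 0.145). Female-biased genes (4 of 8 higher, adjusted p = 0.392) and imprinted genes (6 of 12 higher, adjusted p = 0.915) did not pass, and each had 0 called over all genes and 0 adjusted over the list alone. Among their leading members in the authors' deposited table were A1bg at 2.36, Cdkn1c at 0.54 and Impact at 0.27. The median and the test differed in sign for both lists.

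Acute phase and stress genes were lower as lists. Acute phase genes fell, with 15 of 18 lower and a median of -0.36 (adjusted p = 0.0109), and in the authors' deposited table Socs3 stood at -1.82, Fgb at -0.65, Fgg at -0.55 and Fga at -0.58. Immediate early and dissociation stress genes fell, with 12 of 15 lower and a median of -0.85 (adjusted p = 0.0148), and Fos at -3.54, Junb at -2.21, Egr1 at -2.19 and Fosb at -3.09 had p of 0.134 to 0.304 in the authors' deposited table. Neither list had a member called over all genes or adjusted over the list alone, and both calls were lost at an inter-gene correlation of 0.05 (adjusted p = 0.0621 for each). The immediate early call was also lost with a mean of at least 50 (adjusted p = 0.0646). Regardless of sign, neither acute phase (adjusted p = 0.153) nor immediate early genes (adjusted p = 0.589) passed. Interferon response genes did not pass (14 of 17 lower, adjusted p = 0.186, 0 called over all genes or adjusted over the list alone), with Mx2 at -0.57 and Bst2 at 0.36 in the authors' deposited table. The correlation within lists could not be estimated, since the table has no library columns. At a preset correlation of 0.05, 9 of the 12 lists that passed at 0.01 passed again, those lost being acute phase, immediate early and pericentral genes.

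Hepatocyte markers were level, and markers of most other liver cell types had lower means without passing the main test. The hepatocyte list had 9 of 18 members higher, a median of -0.01 and an adjusted p of 0.68, led by Foxa1 at -0.58 and Cebpa at -0.36 in the authors' deposited table. Kupffer cell and macrophage markers were lower in 11 of 11 genes (median -0.58, adjusted p = 0.233), sinusoidal endothelial markers in 10 of 11 (median -0.58, adjusted p = 0.526) and stellate cell and fibroblast markers in 11 of 12 (median -0.56, adjusted p = 0.392). Csf1r at -0.92, Timd4 at -0.58, Lyve1 at 0.39, Eng at -0.95, Rgs5 at -0.46 and Pdgfrb at -0.84 led these lists in the authors' deposited table. Lymphocyte (10 of 11 lower, median -0.45, adjusted p = 0.56) and neutrophil markers (7 of 7 lower, median -1.23, adjusted p = 0.159) did not pass either, led by Cd4 at -0.71, Ptprc at -0.73, Cxcr2 at -0.72 and Mmp9 at -1.57 in the authors' deposited table. Some of these counts were low, with Mmp9 at 4.5 in control and 1.5 in Ncaph2-deleted hepatocytes and Cd4 at 11.4 and 6.9. Neither list could be tested with a mean of at least 50 required. Cholangiocyte markers split evenly (4 of 8 higher, median 0.25, test direction lower, adjusted p = 0.526), and of 3 measured erythroid genes 1 was higher (adjusted p = 0.7). Sox9 at -1.07, Alas2 at -0.59 and Hbb-b1 at 0.27 were among the leading members of these lists in the authors' deposited table. Every cell type list had 0 members called over all genes and 0 adjusted over the list alone. The implied standard error was large for these markers, with a median of 1.39 for Kupffer cell genes and 1.70 for endothelial genes against 0.31 for hepatocyte genes, so single markers were not resolved. In the rank version of the list test, Kupffer cell and macrophage (adjusted p = 0.0399) and neutrophil markers (adjusted p = 0.0473) fell. Set against expression-matched draws, which ignore the spread between libraries, the medians of Kupffer cell (adjusted p = 0.00015), endothelial (8.57e-05), stellate (0.00065) and neutrophil genes (0.024) were lower, as was that of interferon genes (0.03), and that of PPARalpha targets was higher (0.0476). Mitochondrially encoded genes were not analysed here.

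**Figure D3:**
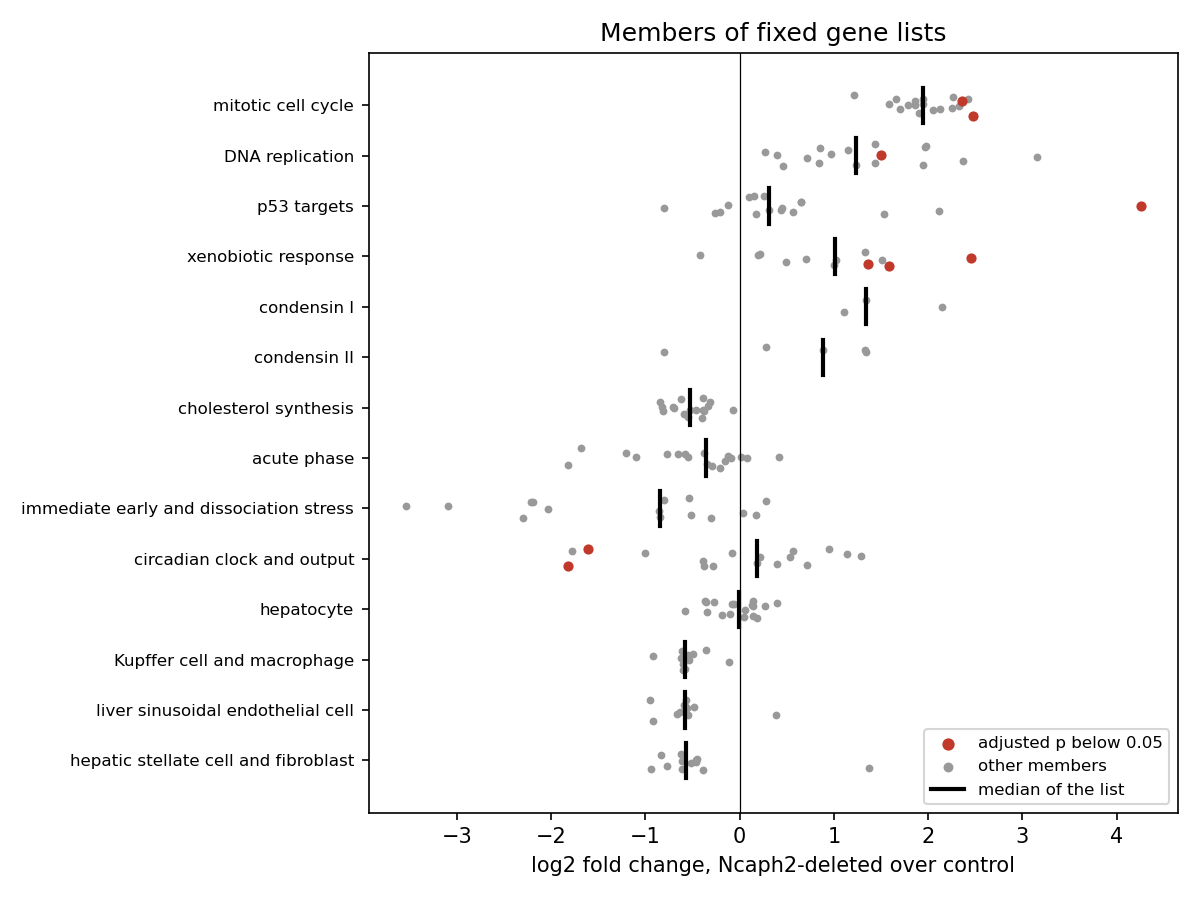
Log2 fold change of Ncaph2-deleted over control for the measured members of 14 fixed gene lists, 1 point per gene with a finite value, red where the authors' adjusted p was below 0.05, with a bar at each list's median. The mitotic list lies wholly above 0 (median 1.94) and the cholesterol synthesis list wholly below it (median -0.52).

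Higher and lower genes were close to balance, which the division by size factors largely sets, so a shift shared by all genes cannot be seen in these values. Of 13938 genes with a finite log2 fold change, 45.3% were higher in Ncaph2-deleted hepatocytes, with a median of -0.04, and of 8948 genes with a mean of at least 50, 51% were higher, with a median of 0.01. Among those 8948 genes, the interval implied by the authors' p lay within a log2 fold change of 1 on either side of 0 for 5104 genes (57%) and within 0.58 for 1694 genes (18.9%). These shares are of all 8948 genes, of which 8799 had an interval. The implied error is unreliable near a log2 fold change of 0 and can be too small there. The counts of 5104 and 1694 therefore do not show that these genes were unchanged. Even by the interval implied by p, changes above 0.58 were not excluded for most of the 8948 genes. With an error pooled over genes of similar expression, chosen after the data were seen, the counts were 6634 and 32. The median pooled error was 0.31, at which the interval reached beyond 0.58 even for a gene without change. The count of 32 was limited by that width, so no conclusion is drawn from it.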

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

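The pooled error and the test of lists in either direction were chosen after seeing the data, and all other alternatives were planned. The 58 genes called became 23 at an adjusted p below 0.01, 111 at 0.1, 93 with adjustment over genes with a mean of at least 10, 13 over genes with a mean of at least 500 (fewer genes tested), 316 under an empirical null (227 higher and 89 lower), whose robust spread of z was 0.771, and 90 after centring (69 higher and 21 lower). The empirical null and centring also adjust over the 14927 genes analysed in place of 22224 tests, which alone gave 70 calls. Centring shifted values by 0.01 only, and 14 of the 20 calls it added to those 70 had an absolute log2 fold change below 0.1, where the implied error is unreliable. All 58 were called again at 0.1, with adjustment over all genes analysed, with a mean of at least 10, under the empirical null and after centring. Ncaph2 passed under the empirical null (adjusted p = 0.0206), which divides z by its robust spread of 0.771 and so enlarges z. It also passed when adjusted over the condensin II list alone, which corrects for 5 genes only. The other adjustments over many genes and centring gave Ncaph2 an adjusted p of 0.262 to 0.355. Of 30 lists, 12 passed in the main test and 8 to 17 under the alternatives, and lists with fewer than 3 members at a mean of at least 50 gave no value there. The clock list turned to higher by ranks (adjusted p = 0.809), without called genes (0.155) and by matched draws of its median (0.0236). Regardless of sign 13 lists passed, 9 of them among the 12: the clock list (9.91e-13), lipogenesis and glycolysis, gluconeogenesis and periportal genes were gained, and genes next to Ncaph2 (0.589), acute phase (0.153) and immediate early genes (0.589) were lost. By matched draws the medians of lipogenesis and glycolysis (0.273), female-biased (0.92), imprinted (0.92) and cholangiocyte genes (0.3) had the opposite sign to the main test. The share of genes higher was 48% with a mean of at least 10, 51% at 50 and 52.9% at 500, against 45.3% for all. With a mean of at least 500, 1999 genes (66.6%) lay within a log2 fold change of 1 and 703 (23.4%) within 0.58. These were fewer genes but larger shares than at 50 (57% and 18.9%). With a mean of at least 10 the shares were 49.6% and 16.6%. All of these shares rest on the implied error, which is unreliable near a log2 fold change of 0. The pooled error left 32 genes within 0.58, a count limited by the width of its interval. No paired analysis was possible because the replicate numbers are shared only between RNA and Hi-C samples and the table has no library columns. For the same reason leaving out a replicate, regrouping samples, count tests with DESeq2 or edgeR, an estimated correlation and levels across the 4 replicates were not run. The shallowest control library, near 4059636 reads, limits what can be said of low genes.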

Other observations

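All tests in this part were chosen after the results were seen. The lists for ribosome biogenesis, endoplasmic reticulum stress, day-peaking, night-peaking and glucocorticoid genes were also written then. Their p-values describe these data and give no independent support. Among called genes that were higher, 9 of 1108 gene ontology terms passed Fisher's exact test, led by cell cycle (15 of 413 genes, adjusted p = 1.46e-07), mitosis (11 of 184, adjusted p = 1.76e-07) and cell division (12 of 246, adjusted p = 1.76e-07). No term passed for the 8 lower genes, and the annotation of 7 called genes was not used here. The authors wrote a note beside 23 genes in their deposited table, all of them called. Ribosome biogenesis genes rose as a list, with 18 of 18 higher, a median log2 fold change of 0.44 and a cameraPR adjusted p of 9.92e-15. Nop58 was the 1 called member and passed the authors' test narrowly (adjusted p = 0.04998). Genes of endoplasmic reticulum stress rose, with 16 of 18 higher, a median of 0.30 and an adjusted p of 8.28e-09, and Herpud1 was called. The p53 targets without Cdkn1a still rose (12 of 16 higher, adjusted p = 1.22e-05). Lists of 7 day-peaking and 6 night-peaking clock genes had medians of -0.28 (adjusted p = 0.00118) and 0.64 (adjusted p = 0.00191).

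The genes in this paragraph were named after their values were seen, and the first 3 did not pass. Ifi202b was listed at 0 in Ncaph2-deleted hepatocytes and at 15.8 in control in the authors' deposited table (adjusted p = 0.308). Gm9000 averaged 160 in control and 1.28 in Ncaph2-deleted cells (adjusted p = 0.343), and Lnx1 86.6 and 5.02 (adjusted p = 0.577), in the authors' deposited table. Esr1, whose name also stands in the genotype label beside the Cre, rose from 862 to 1814 normalised reads in the authors' deposited table (adjusted p = 0.0113). The label was read as a tamoxifen-inducible Cre, so Esr1 reads may include those of a Cre fusion. Gene-level values would not separate such reads from those of the gene, so a rise of the native gene is not shown. Lpin1, a phosphatidate phosphatase, rose from 2356 to 8414 in the authors' deposited table (adjusted p = 0.000464).

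The first pattern is the rise of mitotic and replication genes, whose 35 members had a median log2 fold change of 1.86. A dependence on expression level or depth is argued against, since the upper end of the central 95% of medians of 100000 lists matched on expression was 0.087. Mean levels of 60 markers of other liver cells did not rise with these genes, with 7 of 60 higher and a median of -0.57. A larger share of such cells was still not excluded by the test. With 1 error shared by all markers, which reflects the spread between libraries, the upper 95% bound was 2.70. Control libraries made at another time cannot be told apart from the deletion, because 0 RNA samples are labelled as controls. Loss of Ncaph2 itself, the difference that the design names, stays open and untested. The genotype of the controls is not given in the sources used here, so whether they carried the Cre is not known.

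The second pattern is the movement of clock genes in both directions. Collection at another time of day could produce it, and the 6 night-peaking genes stood 2.30 above the 7 day-peaking genes in mean z, with a 2-sided exact permutation p of 0.0775 over 1716 splits, which leaves it open. A difference in glucocorticoid signalling is a candidate explanation, as a list of 14 targets was higher in the cameraPR test of limma (adjusted p = 0.00118 over 6 lists chosen after the data were seen), with a median of 0.28, 10 members higher and 0 called. Fkbp5 at 2.79-fold and Tsc22d3 at 2.32-fold were higher without passing (adjusted p = 0.133 and 0.651), and Klf9 at 0.82-fold and Sgk1 at 0.97-fold were lower, in the authors' deposited table. These explanations were not separated from each other or from an effect of the deletion.

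The third pattern is that 57.2% of the control level of Ncaph2 transcript remained. Reads from exons outside the deleted part, or cells without recombination, may account for this, and a single value per gene cannot separate them. A regional change could add to the decrease, since the neighbours had a median of -0.27, and the difference of Ncaph2 from that median was -0.54 with a 95% interval of -1.14 to 0.06, so it was not excluded.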
